A study of Homo sapiens with 8 samples.

How the data were processed

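Total RNA of GFP-labelled microglia derived from the H1 line was sequenced in bulk. Per the labels' protocols, the cells were sorted by fluorescence into a lysis reagent, 4 independent batches were prepared in parallel, and RNA was purified on small-elution columns. The labels describe the cells both as derived from induced pluripotent cells and as H1, which is an embryonic stem cell line; H1 is used here. Mono-cultures received IL-34 and M-CSF and tri-cultures no exogenous cytokine, per the labels' protocols.

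The deposited count values are whole numbers of reads per gene, made by the authors with HISAT2 2.1.0 and featureCounts 2.12.3 on GRCh38, per the submitters' processing notes. The annotation release, the use of strand and the handling of reads over overlapping genes are not given in the sources used here. A second deposited table, named as TPM, holds per-library signal values whose totals ran from 0.866 to 1.14 (in units of 1e6) with a geometric mean of 1, so they are TPM rescaled per library and were treated as a signal of unspecified scaling made by the authors. In 5400 genes with high counts in all libraries, the value per count kept a constant ratio between libraries within 0.0583%, and 3 values were listed at 0 where the count was above 0.

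The count table held 78899 genes, of which 39751 had a count and 42163 matched a symbol. GENCODE 29 on GRCh38 gave coordinates and biotypes to 15246 of the tested genes. Genes were filtered with filterByExpr on the group (minimum count 10, minimum total count 15), which left 16249. Of these, 14368 had a symbol and 12772 were protein coding by GENCODE 29. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood, robust, group only, R 4.3.3). Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 fold changes are tri-culture minus mono-culture. Their standard errors are the absolute log2 fold change divided by the square root of the F statistic, an approximation. The common biological coefficient of variation was 0.206. CPM values are means ± SD of 4 libraries.

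On simulated counts for the 16249 genes of this comparison, with 200 genes changed, edgeR recovered 12 of 50 genes changed 1.5-fold (24%), 35 of 50 at 2-fold (70%), 49 of 50 at 4-fold (98%) and 50 of 50 at 8-fold, and called 5 unchanged genes. Small changes are therefore often missed at this number of replicates. Genes with no count in a group are compared with a floor of 3 counts over the group (0.0308 CPM in mono-culture), and for 1 to 3 counts the count ratio is given with a 95% interval. Floors and intervals cover counting error only.

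Before the data were examined, 27 gene lists, the tests, the alternatives and a rule for named genes were fixed. Lists with at least 5 tested members, 25 of 27, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 25. By this test 5 lists were higher and 7 lower. With an estimated correlation none of these calls held. At an unadjusted p under 0.05 that setting gave 2 lists higher and 1 lower. The median, the mean and the test differed in sign for the lists of type I interferon, LXR, immediate early, neuron, and monocyte and border macrophage genes, none of which was called. Named genes were the 10 largest increases and 10 largest decreases among called genes with a symbol, a mean of at least 5 CPM and the same direction in all 4 batch pairs, the up to 3 members of each list with the smallest adjusted p, and P2RY12, TMEM119, CX3CR1, TREM2, APOE, SPP1, AIF1 and CSF1R whatever their p. Other genes named were chosen after their values were seen. They were HLA-DRA, CD74, CIITA, PTPRC, COL3A1, members of the fixed lists named to show which ones moved, and the genes of the added lists in the closing part. Some genes that the rule names are not reported here.

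The labels give each library a batch number from 1 to 4 shared between the groups, so the numbers pair the libraries. Deviations from the group means correlated within pairs at 0.185, 0.127, 0.264 and 0.0796, and the second principal component parted batches 1 and 2 from 3 and 4 in both groups. Each batch holds 1 library per group, so no test within a batch was possible, and a fit with the batch as a block was an alternative. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 9.21 to 65.1), so no library was counted as a repeat. The labels call the batches independent, and p-values measure the spread between these batches.

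The alternatives were other scaling (DESeq2 1.42.0 size factors, library size only, upper quartile), other filters, DESeq2, limma-trend on the deposited signal values, the block, a minimum fold, protein-coding genes, each library or batch left out, and other list tests. Protein coding was taken from GENCODE 29, so genes without a biotype there were left out of that run. Each run with libraries left out filtered the genes anew, so the tested members of a list could differ. Because strand use is not given, genes with exons on the opposite strand over more than 20% of their exon bases are uncertain: HTR2B (24.9%), ICAM1 (23.6%), HLA-F (28.5%), ACAT2 (52.3%), ATF5 (21.2%) and PAX6 (26.1%). The most abundant single gene in every library lies in the ribosomal DNA region and took 2.94% ± 0.527 of counts in mono-culture and 2.59% ± 0.158 in tri-culture (n = 4 each, 2-sided exact permutation p = 0.257). Across 15246 genes, the log2 fold change and exon length had a Spearman correlation of 0.0217; genes are not independent replicates.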

Results

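Bulk RNA sequencing was carried out on microglia derived from the human embryonic stem cell line H1, an established pluripotent line, and kept either alone (mono-culture, 4 libraries) or together with other cells (tri-culture, 4 libraries). Microglia are the resident macrophages of the brain. They carried a GFP label and were recovered from both kinds of culture by fluorescence-activated sorting 2 weeks after plating. The mono-cultures received the CSF1 receptor ligands IL-34 (100 ng/mL) and M-CSF (10 ng/mL), whereas the tri-cultures received no added cytokine, so the presence of other cells and the absence of the supplement changed together. The partner cells of the tri-culture are not named in the labels used here. Each group held 1 library of each of 4 batches. The mono-culture libraries held 30934258, 19281467, 33363972 and 17037481 counts and the tri-culture libraries 22305977, 24491765, 20791239 and 17602010, a difference that did not pass a 2-sided exact permutation test (p = 0.429). The share of counts from mitochondrial genes was 6.19% ± 1.57 in mono-culture and 5.65% ± 0.394 in tri-culture (n = 4 each, 2-sided exact permutation p = 0.714). The pan-leukocyte gene PTPRC stood at 620.1 ± 46.8 and 632 ± 61.9 CPM (counts per 1e6 counts of the library), and the microglia and macrophage marker AIF1 at 359 ± 49.6 and 416 ± 135 CPM, in mono-culture and tri-culture respectively, without a difference past the test. AIF1 varied over tri-culture libraries 1 to 4, at 591, 450, 287 and 335 CPM. Not all myeloid markers were level: ITGAM fell from 173 ± 32.3 to 61.3 ± 33.4 CPM (log2 fold change -1.50 ± 0.33 SE, edgeR, adjusted p = 0.00383).

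The comparison asks how the transcriptome of the sorted microglia differed between the culture types. The first principal component of the log2 CPM values held 67.8% of the variance and set the mono-culture libraries, at scores between -69.9 and -62.1, apart from the tri-culture libraries, at 56.8 to 73.7. Of 16249 genes tested, 4373 (26.9%) differed at an adjusted p under 0.05, 2261 higher and 2112 lower in tri-culture, and 1314 and 814 of these changed by over 2-fold. The direction was the same in all 4 batch pairs for 4293 of the 4373 genes. Of the 2261 higher genes, 204 had 3 counts or fewer over all mono-culture libraries. With library size as the only scaling, 2829 genes were higher and 1663 lower, and the median log2 fold change of all tested genes was 0.12 instead of 0.02; higher genes then made up 63.0% of the calls instead of 51.7%.

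**Figure D1:**
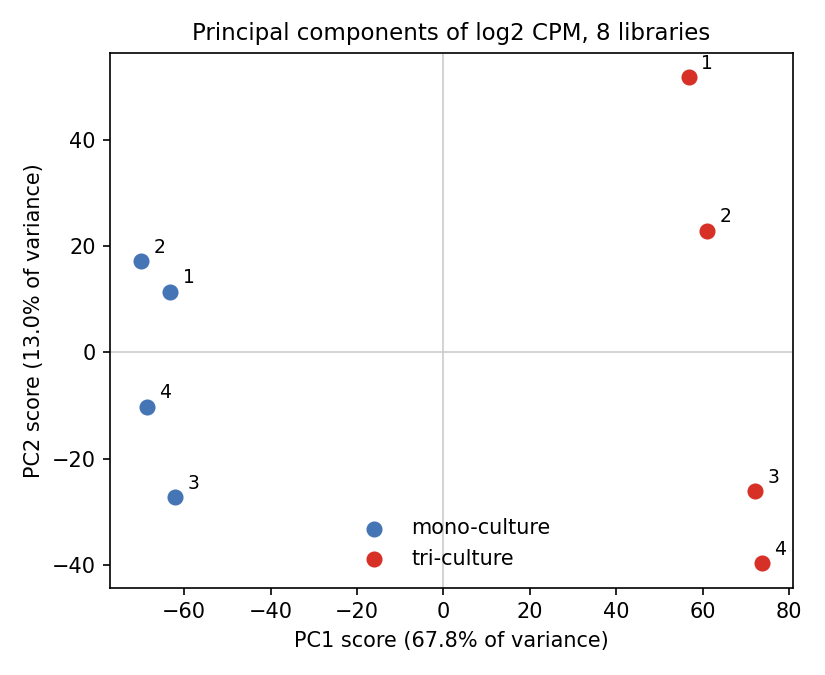
Scores of the 8 libraries on the first (x axis, 67.8% of variance) and second (y axis, 13.03% of variance) principal components of log2 CPM; points are libraries, coloured by culture type and numbered by batch. The culture types part on the first component, and batches 1 and 2 lie above batches 3 and 4 within each culture type on the second.

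Transcripts of the MHC class II antigen presentation pathway rose together in tri-culture. All 12 tested genes of the list were higher, with a median log2 fold change of 4.85, and all 12 passed when adjusted over the list alone. HLA-DPB1, the beta chain of HLA-DP (ENSG00000223865, chromosome 6, 33075926 to 33087201), stood at 6.23 ± 2.30 CPM in mono-culture and 605 ± 92.1 CPM in tri-culture (SD, n = 4 each), a 99.2-fold difference (log2 fold change 6.63 ± 0.26 SE, adjusted p = 8.37e-09). HLA-DQA1 rose 126-fold, from 1.30 ± 0.644 to 160.3 ± 18.6 CPM. HLA-DRA went from 90.0 ± 24.0 to 3148 ± 533 CPM, the invariant chain gene CD74 from 489 ± 110.3 to 5562 ± 1079 CPM, and CIITA, the master transactivator of the class II genes, from 12.4 ± 0.749 to 207 ± 47.8 CPM. HLA-DRB5 rose 23.6-fold. Reads can be shared between HLA genes of near-identical sequence, so the values of single HLA genes, HLA-DRB5 above all, are uncertain. The list was higher against all other genes (camera, adjusted p = 5.24e-17), with adjusted p = 0.0535 with an estimated correlation between genes. Markers of astrocytes were higher in the same libraries (14 of 17 tested), as were genes of dendritic cells, which carry class II molecules. Of a dendritic list written after the data were seen, 7 of 13 tested genes were higher, without CD207, FCER1A and NDRG2, which had been seen beforehand. CLEC10A, a lectin of dendritic cells and macrophages, rose from 13.9 ± 5.55 to 133 ± 44.7 CPM. Among MHC class I genes, 5 of 14 were higher and none lower, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.360). The light chain gene B2M stood at 1343 ± 164 and 1480.2 ± 434 CPM, without a difference past the test.

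**Figure D2:**
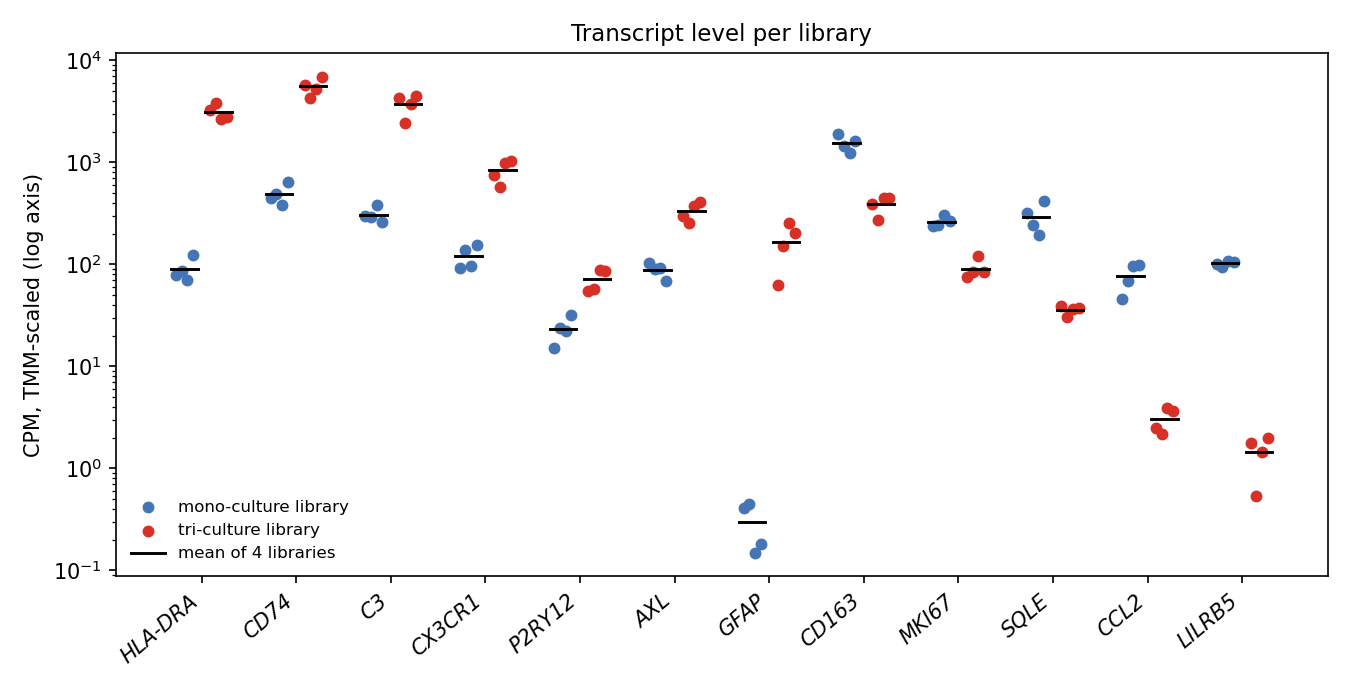
Transcript level of 12 genes (x axis) in CPM on a log axis (y axis); points are the 4 libraries of each culture type and black bars are their means. HLA-DRA, CD74, C3, CX3CR1, P2RY12, AXL and GFAP were higher and CD163, MKI67, SQLE, CCL2 and LILRB5 lower in tri-culture, with no overlap between the 4 libraries of each group in any of the 12 genes.

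Genes of homeostatic microglia moved in both directions, with more of them higher. Of 20 tested genes, 9 were higher, 4 lower and 7 did not pass; adjusted over the list alone, 10 were higher and 5 lower. CX3CR1, the fractalkine receptor (ENSG00000168329, chromosome 3, 39263494 to 39281735), rose 6.94-fold from 120.2 ± 30.7 to 833 ± 214 CPM (log2 fold change 2.79 ± 0.22 SE, adjusted p = 1.77e-06). OLFML3, a secreted olfactomedin-family protein, rose 7.12-fold to 208 ± 17.7 CPM, and P2RY12, the purinergic receptor that guides process extension, rose 3.10-fold from 23.2 ± 6.96 to 71.6 ± 17.6 CPM. SALL1, a transcription factor of microglia that neural progenitors and glia also express, had no count in mono-culture and 9.66 ± 4.38 CPM in tri-culture, at least 311-fold higher against a floor of 3 counts over the group. The members that fell included BIN1 and MAF, at log2 fold changes of -0.78 and -0.80. TMEM119 stood at 22.5 ± 2.16 and 14.7 ± 6.98 CPM (adjusted p = 0.0855), and with the batch as a block it was called lower (log2 fold change -0.70, adjusted p = 0.00761), as it was without tri-culture library 1 (adjusted p = 0.000245). CSF1R stood at 1391 ± 102 and 1822 ± 508 CPM (adjusted p = 0.174), and without tri-culture library 2 it was called higher (adjusted p = 0.00964). The list passed narrowly (camera, adjusted p = 0.0459), with adjusted p = 0.284 with an estimated correlation and 0.0677 with the batch as a block. It also missed the threshold without mono-culture library 3 (adjusted p = 0.0679) or tri-culture library 1 (0.0837), and with library size only (0.0672) or upper quartile factors (0.0599). Astrocyte markers were higher in the same libraries, 14 of 17 tested.

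Genes linked to disease-associated and lipid-associated microglia split, with 7 higher, 10 lower and 7 not passing of 24 (8 and 10 adjusted over the list alone; camera, adjusted p = 0.360). The receptors AXL and TREM2 rose 3.76-fold and 2.02-fold, to 332 ± 68.9 and 457 ± 98.5 CPM. CH25H, cholesterol 25-hydroxylase (ENSG00000138135, chromosome 10, 89205629 to 89207314), fell from 17.8 ± 4.49 to 0.118 ± 0.101 CPM, a log2 fold change of -7.21 ± 0.39 SE (adjusted p = 6.27e-08). Cathepsins B and L, FABP5 and PLIN2 were also lower. SPP1, among the most abundant transcripts, stood at 10966 ± 2975 and 10583 ± 4407 CPM (adjusted p = 0.927). APOE passed only narrowly, at 566 ± 196 and 1043 ± 429 CPM (adjusted p = 0.0485, between 0.00018 and 0.506 over the alternatives), and the call was lost without mono-culture library 2, 3 or 4 (adjusted p = 0.0696, 0.109 and 0.134) or tri-culture library 1, 2 or 3 (0.0753, 0.156 and 0.0723).

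In the list of the CSF1 receptor and its ligands, 3 of 7 tested genes were higher, and none of the 3 encodes the CSF1 receptor or M-CSF. They were CSF2RA, the GM-CSF receptor alpha chain (2.82-fold, to 227 ± 15.5 CPM), CSF3R, the G-CSF receptor (9.37-fold, to 15.3 ± 4.70 CPM), and PTPRZ1, a receptor phosphatase abundant in glia that also binds IL-34, which had no count in mono-culture and was at least 442-fold higher at 13.8 ± 6.85 CPM. Adjusted over the list alone, 3 were higher and 1 lower. The list passed (camera, adjusted p = 0.0223), with adjusted p = 0.284 with an estimated correlation and 0.0677 with the batch as a block. It did not pass in the run kept to genes that GENCODE 29 calls protein coding (adjusted p = 0.132). That run left out the Ensembl entry used for CSF2RA, which has no biotype in that release, so the lost call says nothing about coding status. Where a symbol has several entries, the lists used the entry with the most counts. In these libraries 14 of 17 tested astrocyte markers were also higher. Of 22 genes of TGF-beta signalling, 8 were higher and 6 lower (10 and 6 adjusted over the list alone; camera, adjusted p = 0.249). The inhibitory genes SMAD6 and SKIL rose 4.602-fold and 3.14-fold, whereas LTBP2, a latent TGF-beta binding protein, fell from 148 ± 31.9 to 28.6 ± 9.13 CPM.

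Scavenger receptors and markers of border-associated macrophages were among the genes that fell. CD163, the haemoglobin scavenger receptor, decreased from 1548 ± 284 to 391 ± 81.3 CPM (log2 fold change -1.99 ± 0.19 SE, adjusted p = 6.50e-06), COLEC12 from 177 ± 47.0 to 22.6 ± 8.33 CPM, the hyaluronan receptor LYVE1 from 19.5 ± 12.8 to 0.613 ± 0.434 CPM, and the mannose receptor MRC1 from 1149 ± 357 to 384 ± 99.3 CPM. Of 22 phagocytic and scavenger receptors, 5 were higher and 10 lower (5 and 11 adjusted over the list alone), and the list missed the threshold (camera, adjusted p = 0.0633). It was called lower with library size only (0.0368) or upper quartile factors (0.0379), and without mono-culture library 2, 3 or 4 (0.0499, 0.0294 and 0.0459) or tri-culture library 3 or 4 (0.0483 and 0.0452). The higher ones were AXL, MERTK and the Fc gamma receptors FCGR2A, FCGR2B and FCGR3A. In the list of monocytes and border macrophages, 6 of 13 genes were lower and 5 higher, the same counts adjusted over the list alone (camera, adjusted p = 0.731). Its lower members were CD163, COLEC12, LYVE1, MRC1, F13A1 and CD44, and its higher members were the monocyte genes CCR2, LYZ, VCAN, S100A8 and S100A9. Of 16 complement genes, 4 were higher and 7 lower (5 and 8 adjusted over the list alone; camera, adjusted p = 0.360). C3, the central complement component, rose 12.1-fold from 308 ± 52.0 to 3719 ± 891 CPM, and the complement receptor VSIG4 fell from 789 ± 78.5 to 328 ± 62.4 CPM.

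Most NF-kB cytokine and chemokine genes that changed were lower. Of 24 tested, 13 were lower, 2 higher and 9 did not pass (14 and 3 adjusted over the list alone; camera, adjusted p = 0.000636, and adjusted p = 0.235 with an estimated correlation). CCL2, a monocyte chemoattractant, fell from 77.3 ± 24.6 to 3.04 ± 0.853 CPM (log2 fold change -4.67 ± 0.27 SE, adjusted p = 1.21e-07), and the adhesion molecule ICAM1 from 109 ± 12.9 to 42.6 ± 7.25 CPM, the latter with antisense genes over 23.6% of its exon bases. The 2 that rose were the inflammasome substrates IL18, 14.1-fold to 16.6 ± 4.11 CPM, and IL1B, from 35.2 ± 14.01 to 96.6 ± 3.19 CPM. Astrocyte markers (14 of 17) and dendritic genes (7 of 13) were higher in these libraries. The type I interferon response list held 5 higher and 3 lower of 32 genes, the same adjusted over the list alone (camera, adjusted p = 0.8295), with RSAD2 2.48-fold higher and the interferon-induced lectin SIGLEC1 lower, at 142 ± 44.3 and 46.3 ± 19.9 CPM. Immediate early and heat shock genes held 7 higher and 5 lower of 24 (8 and 6 adjusted over the list alone; camera, adjusted p = 0.787). NR4A1 rose 10.7-fold to 7.99 ± 3.99 CPM, and FOS fell from 104 ± 7.29 to 40.8 ± 3.98 CPM.

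Cholesterol synthesis genes were lower almost throughout. Of 24 tested, 22 were lower and none higher, the same counts adjusted over the list alone, with a median log2 fold change of -1.49 (camera, adjusted p = 2.03e-12, and adjusted p = 0.284 with an estimated correlation). SQLE, squalene epoxidase (ENSG00000104549, chromosome 8, 124998497 to 125022283), fell from 293 ± 97.5 to 35.9 ± 3.89 CPM (log2 fold change -3.03 ± 0.21 SE, adjusted p = 5.22e-07). ACAT2 fell from 73.2 ± 20.7 to 16.5 ± 3.68 CPM, and 52.3% of its exon bases lie under exons on the opposite strand, so its value is uncertain. Beside these decreases, 14 of 17 astrocyte markers were higher in the same libraries. LXR targets and lipid efflux genes split, with 4 higher and 5 lower of 13, the same adjusted over the list alone (camera, adjusted p = 0.520). Those lower included the lipogenic genes FASN (145 ± 45.8 to 26.1 ± 13.96 CPM) and SCD (855 ± 359.8 to 219 ± 44.96 CPM) and the phospholipid transfer protein PLTP.

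Lysosomal and glycolytic genes that changed were mostly lower, and few respiratory chain genes passed the test. Of 31 lysosomal genes, 11 were lower and 1 higher, the same adjusted over the list alone (camera, adjusted p = 0.00850, and adjusted p = 0.432 with an estimated correlation). The membrane protein LAMP1 fell from 399 ± 52.7 to 203 ± 33.4 CPM. As for the groups above, 14 of 17 astrocyte markers and 7 of 13 dendritic genes were higher in the libraries in which lysosomal, glycolytic and respiratory chain lists were lower. Of 22 glycolysis genes, 7 were lower and 1 higher (8 and 1 adjusted over the list alone; camera, adjusted p = 0.0107, and adjusted p = 0.284 with an estimated correlation). Enolase, ENO1, fell from 1618 ± 157 to 952 ± 92.4 CPM, and the glucose transporter SLC2A1 rose 6.88-fold to 3.81 ± 1.13 CPM. In the oxidative phosphorylation list only 4 of 41 genes passed over all genes, all lower, and 1 adjusted over the list alone, with a median log2 fold change of -0.25. COX7A2, a subunit of cytochrome c oxidase, fell from 116 ± 3.96 to 72.2 ± 16.1 CPM. With the batch as a block 13 of the 41 were lower. The list passed (camera, adjusted p = 0.00204), with adjusted p = 0.679 with an estimated correlation, and without tri-culture libraries 3 and 4, a choice made after seeing the data, it did not (adjusted p = 0.902), nor did it with the fry rotation test (0.183).

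Cell cycle genes were lower in tri-culture. Of 29 tested, 21 were lower and none higher, and 25 were lower adjusted over the list alone, with a median log2 fold change of -0.80 (camera, adjusted p = 6.50e-10, and adjusted p = 0.284 with an estimated correlation). The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) fell from 262 ± 30.6 to 90.8 ± 19.7 CPM (log2 fold change -1.53 ± 0.15 SE, adjusted p = 9.18e-06), the mitotic kinase PLK1 from 27.1 ± 4.96 to 10.4 ± 0.538 CPM, and the transcription factor E2F1 from 24.9 ± 6.32 to 8.12 ± 1.61 CPM. In the same libraries 14 of 17 astrocyte markers and 7 of 13 dendritic genes were higher. Genes of the integrated stress response held 8 lower and none higher of 19, the same adjusted over the list alone (camera, adjusted p = 0.000636, and adjusted p = 0.284 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, fell from 16.1 ± 5.59 to 1.71 ± 0.420 CPM, and PSAT1, a serine synthesis enzyme, from 55.9 ± 25.7 to 16.4 ± 3.06 CPM. Without tri-culture libraries 1 and 2, a choice made after seeing the data, PSAT1 did not pass (adjusted p = 0.0511).

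Markers of other cell types also differed between the sorted samples. Of 17 tested astrocyte markers, 14 were higher and 1 lower (15 and 2 adjusted over the list alone), with a median log2 fold change of 5.78, or 5.24 with genes at 0 counts set to the floor (camera, adjusted p = 1.27e-09, and adjusted p = 0.284 with an estimated correlation). GFAP, the astrocytic intermediate filament (ENSG00000131095, chromosome 17, 44903161 to 44916937), stood at 0.296 ± 0.153 CPM in mono-culture and 167 ± 81.1 CPM in tri-culture (log2 fold change 9.15 ± 0.51 SE, adjusted p = 8.27e-08). The water channel AQP4 and the neurotrophin receptor NTRK2 had no count in mono-culture and were at least 747-fold and 1183-fold higher. FABP7 had 1 count in mono-culture and 1124 in tri-culture, a depth-corrected ratio of 1250.2 (95% interval 224 to 49422, counting error only). Of 6 neural progenitor genes, 4 were higher, among them SOX2 (at least 457-fold, 14.1 ± 5.63 CPM), and 2 were lower, NES and VIM, which microglia also express (camera, adjusted p = 0.0980). Of 23 neuronal genes in the list only 9 passed the filter on counts, and of these 4 were higher and 3 lower (camera, adjusted p = 0.620). GAP43, a growth cone protein, was at least 214-fold higher at 6.59 ± 2.18 CPM, whereas the neurofilament-related gene INA fell from 67.9 ± 20.6 to 5.99 ± 3.24 CPM. Oligodendrocyte lineage genes held 3 higher and 1 lower of 7 (4 and 2 adjusted over the list alone; camera, adjusted p = 0.249), and the list was called higher by limma-trend on the deposited values plus 1 (adjusted p = 0.00935) or plus 0.1 (0.00707). The counts for neural progenitor and neuronal genes were the same adjusted over their lists alone. The neural progenitor list was called higher without any 1 library other than tri-culture library 2, for instance without tri-culture library 1 (camera, adjusted p = 0.000354). The neuronal list was called higher without mono-culture library 1, 2 or 4 (0.0391, 0.0292 and 0.0274) or tri-culture library 1 (0.00519). These runs filtered the genes anew and tested 16670 to 17167 genes against 16249, so other list members could enter. The neural progenitor median was 7.29 without tri-culture library 1, against 3.87. Both lists were also called higher with no filter (camera, adjusted p = 2.46e-05 and 0.00108). A dependence on single libraries therefore cannot be told from the change in filtered genes.

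Of 7 mesenchymal genes, 3 were higher and none lower (4 and 0 adjusted over the list alone; camera, adjusted p = 0.0223, and adjusted p = 0.432 with an estimated correlation). The call was lost without tri-culture library 1 (adjusted p = 0.0555), without batch 1 (0.0894) or 3 (0.0673), and with a filter of 1 CPM in 4 libraries (0.0740). TAGLN, an actin-binding protein of smooth muscle and fibroblasts, rose 4.08-fold to 9.73 ± 1.43 CPM. THY1 had 3 counts in mono-culture and 163 in tri-culture, a ratio of 60.4 (95% interval 20.3 to 296). COL6A3 passed only narrowly (edgeR, adjusted p = 0.0485), with the same direction in 2 of 4 batch pairs, and lost its call in 11 alternative runs. It stood at 0.987 ± 0.344 CPM in mono-culture and at 2.43, 1.10, 7.71 and 1.25 CPM in tri-culture libraries 1 to 4, so library 3 carried most of the increase. Endothelial genes held 1 higher (PECAM1, also a myeloid gene, 271 ± 35.7 to 488 ± 56.5 CPM) and 1 lower (TIE1, 2.69 ± 0.523 to 0.458 ± 0.132 CPM) of 5, the same adjusted over the list alone (camera, adjusted p = 0.549). In the lists with too few tested members for the list test, neither of the 2 mast cell tryptase genes left from the other blood lineages changed, and of 3 pluripotency genes DNMT3B rose 2.33-fold, LIN28B was lower and SALL4 did not pass, the same adjusted over these lists alone. The LIN28B call was lost without mono-culture library 3 (adjusted p = 0.0551) or 4 (0.0599).

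**Figure D3:**
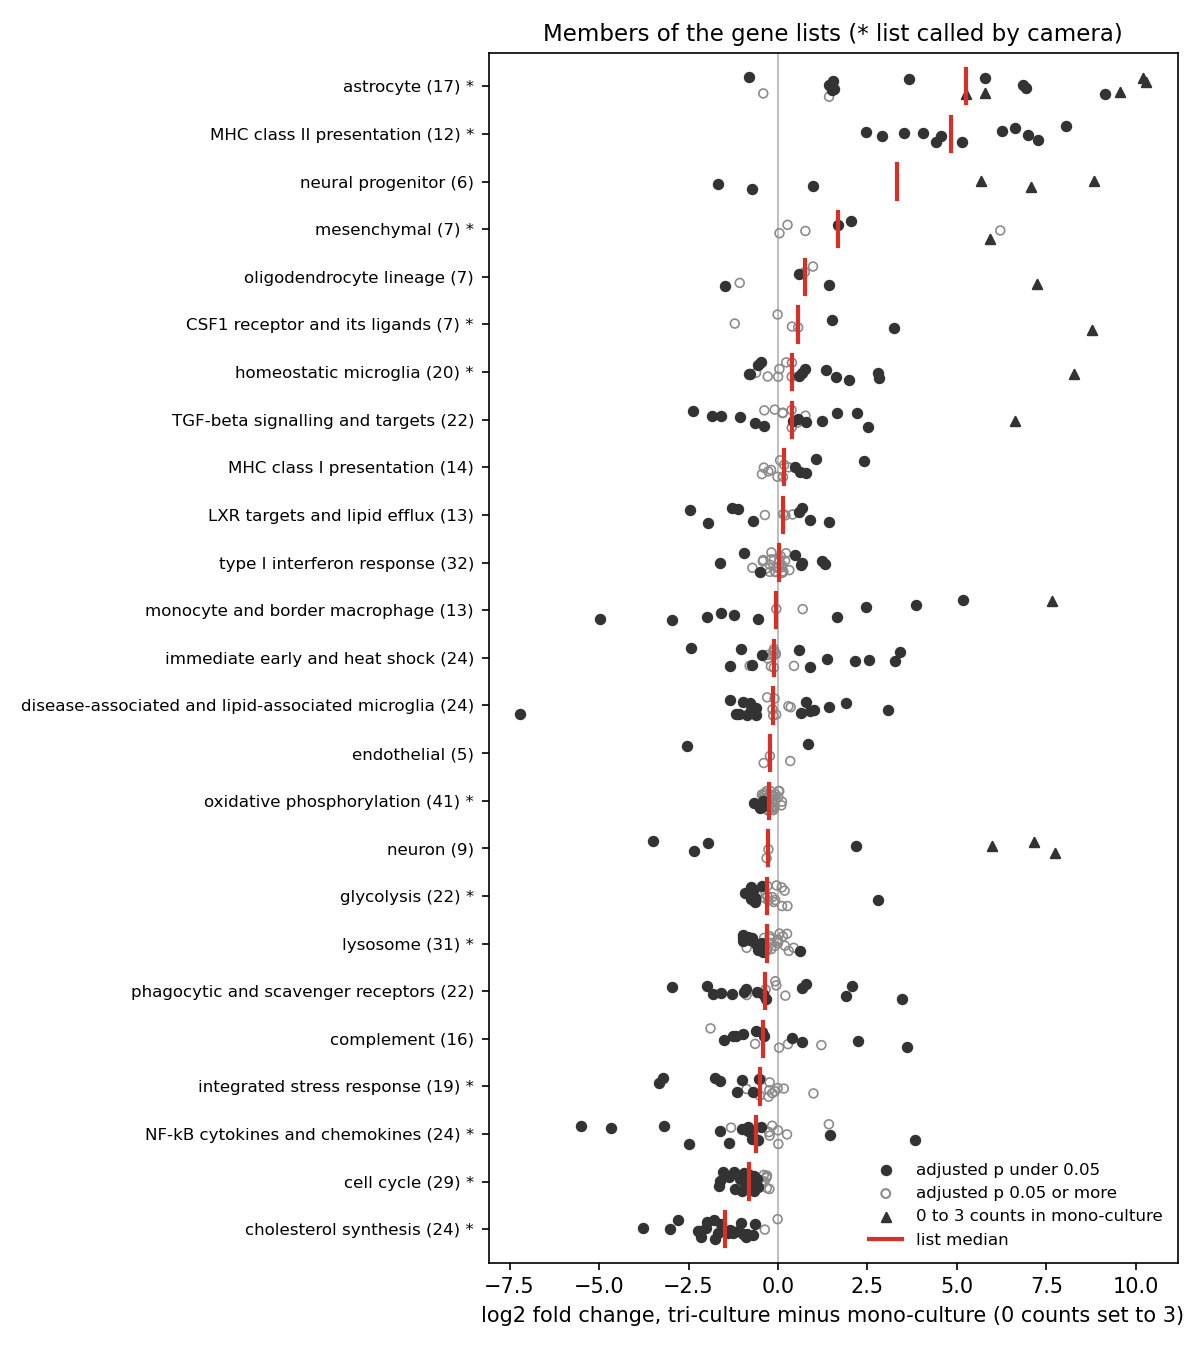
Log2 fold change of each tested member (x axis, tri-culture minus mono-culture, genes with 0 counts set to 3 counts) of the 25 tested gene lists (y axis, with the number of tested members); filled symbols passed the test over all genes, triangles had 0 to 3 counts in mono-culture, red bars are list medians and asterisks mark lists called by camera. All 12 MHC class II genes lie right of 0, and 22 of 24 cholesterol synthesis genes are filled symbols left of 0.

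Among genes averaging at least 5 CPM that moved the same way in all 4 batch pairs, the 10 with the largest increases were NTRK2, AQP4, GPM6A, SOX2, PTPRZ1, FCER1A, FABP7, LINC00461, KCNN3 and GFAP. Of these, FCER1A, the alpha chain of the high-affinity IgE receptor (ENSG00000179639, chromosome 1, 159289714 to 159308224), is a gene of mast cells, basophils and dendritic cells, and rose from 0.0865 ± 0.0723 to 87.6 ± 28.5 CPM (log2 fold change 9.96 ± 0.41 SE, adjusted p = 8.37e-09). The neuronal membrane glycoprotein gene GPM6A had no count in mono-culture and was at least 518-fold higher at 16.0 ± 6.29 CPM. The 10 largest decreases were CH25H, LILRB5, ECM1, FABP4, HTR2B, BMP2, LYVE1, MYOZ2, PLPP4 and RNF128. LILRB5, an inhibitory leukocyte receptor (ENSG00000105609, chromosome 19, 54249431 to 54257301), fell from 102 ± 5.32 to 1.44 ± 0.642 CPM (log2 fold change -6.17 ± 0.26 SE, adjusted p = 8.82e-09). The fatty acid-binding protein gene FABP4 fell from 365 ± 163 to 6.79 ± 3.46 CPM, the extracellular matrix gene ECM1 from 90.9 ± 24.7 to 1.63 ± 0.640 CPM, and the growth factor gene BMP2 from 13.7 ± 4.09 to 0.394 ± 0.0911 CPM.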

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

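In 226 groups of 4 libraries, over named genes and list means, 7 held a library whose gap to the nearest other exceeded Dixon's 95% critical value for 4 samples. Chance alone gives about 1 in 20 such groups. CH25H in mono-culture library 1 was at 11.1 CPM against 19.4 to 20.7 CPM in the other 3. CSF3R in mono-culture library 1 was at 2.74 CPM, and the highest of the other 3 at 1.28 CPM. NDUFS1, a complex I subunit, was at 158 CPM in mono-culture library 2 against 187 to 189.6 CPM in the others. SOX2 in tri-culture library 1 was at 5.79 CPM and the lowest of the other 3 at 15.6 CPM. HLA-DRB5 in tri-culture library 3 was at 185 CPM against 207 to 211 CPM. TRIB3 in tri-culture library 1 was at 2.34 CPM against 1.47 to 1.54 CPM. The mean log2 CPM of the phagocytic and scavenger receptor list was 6.72 in tri-culture library 2 against 7.07 to 7.14 in the others. No explanation was tested for these libraries.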

How the results depend on the processing

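Some alternatives were chosen after the data were seen. They left out tri-culture libraries 1 and 2, tri-culture libraries 3 and 4, or the cell type lists with genes of 3 or fewer mono-culture counts. No named gene or list called in the first analysis changed direction in any alternative run. Of the named genes not called, AIF1 (log2 fold change -0.22 to 0.54), SPP1 (-0.32 to 0.12) and SALL4 (-0.11 to 0.55) changed sign. The median of the neuronal list went from -0.27 to as high as 3.97 (without batch 1), in a run that filtered the genes anew. The medians of the LXR, complement, endothelial, immediate early, monocyte and border macrophage, and type I interferon lists, none called, also changed sign in some alternatives. Library size only gave 2829 genes higher and 1663 lower, upper quartile factors 2723 and 1773, no filter 2715 and 2279, and DESeq2 2860 and 2377. With its filter, limma-trend on the deposited values gave more genes lower than higher, 1568 higher and 1771 lower with 1 added and 1554 and 1756 with 0.1 added, whereas without a filter and with 1 added it gave 1525 and 1309; the cause was not tested. With a log2 fold change over 1, by construction fewer, 1314 genes were higher and 814 lower. Leaving out a library or a batch gave 1651 to 2311 genes higher and 1539 to 2135 lower, with fewer libraries. With the batch as a replicate block 2370 genes were higher and 2363 lower, 4238 of the 4373 called genes among them. Beside the homeostatic and CSF1 receptor lists, TMEM119 (adjusted p = 0.00761) and COL6A3 (0.0678), the block changed no call of a list or named gene.

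Lists called higher numbered 3 with the replicate block, 3 with protein-coding genes, and between 3 (without batch 3) and 7 (without mono-culture library 1, 2 or 4) with a library or batch left out; 7 to 8 were then called lower. With an estimated correlation 0 were higher and 0 lower, and 0 and 0 with the replicate block as well. The fry rotation test, which asks whether the genes of a list move on balance one way and does not set them against other genes, called 10 higher. The cause of these differences was not tested. DESeq2 and the minimum fold give no list test. Without tri-culture libraries 1 and 2, 2824 genes were higher and 2963 lower, and without libraries 3 and 4, 2262 and 2097. Striking the cell type lists and genes with 3 or fewer mono-culture counts from the first analysis left 2036 higher and 2097 lower. Nothing was fitted anew there, so the calls that remained were the same by construction. The struck lists also held genes of macrophages, such as CD163 and MRC1. Depth limits genes near the floor, and on simulated data 24% of genes changed 1.5-fold were recovered.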

Other observations

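Genes of fatty acid synthesis and desaturation fell with those of cholesterol synthesis. Of 11 tested lipogenic targets of SREBP1, a list written after FADS2 and PNPLA3 had been seen, 10 were lower and 1 higher, with a median log2 fold change of -1.67. Without these 2 genes and without FASN and SCD, described above, 6 of 7 were lower and 1 higher. The desaturase genes FADS2 and FADS1 changed by -3.00 ± 0.33 and -2.21 ± 0.18 (log2, SE), and the lipid droplet gene PNPLA3 by -2.88 ± 0.26. The elongase gene ELOVL6 was higher, at 2.15 ± 0.42, but scarce, at 0.198 CPM (19 counts) in mono-culture and 0.890 CPM (78 counts) in tri-culture. Of 16 genes of dendritic cells, 10 were higher and 1 lower in tri-culture; CD207, FCER1A and NDRG2 had been seen before the list was written, and without them 7 of 13 were higher. CD207, the langerin of Langerhans cells, went from 0.0876 to 48.3 CPM, and CLEC10A from 13.9 to 133 CPM, while BATF3 was lower at -1.47 ± 0.27.

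COL3A1, a fibrillar collagen of mesenchymal cells, was uneven: 2.53, 0, 3.34 and 0 CPM in mono-culture libraries 1 to 4, and 203, 0, 222 and 81.7 CPM in tri-culture libraries 1 to 4 (edgeR, adjusted p = 0.0505, and 2.63e-05 with the batch as a block). The macrophage gene CD68 had only 0.618 and 0.335 CPM, and 81.7% of its exon bases are shared on the same strand with another gene of GENCODE 29. How reads over both were counted is not given in the sources used here, so its value is uncertain.

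Tests chosen only after the result was seen were those of neurons, of shared HLA reads, of a common source with astrocyte RNA and of dilution. The bounds of the dendritic test were set before its result, but its gene list was written after the data were seen. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many genes (4373 against 0 at most in the others). Each other split mixes the culture types, which adds their difference to the spread within its groups. A share of 1 in 35 lies under 0.05, but only with the batch pairs set aside, so chance is not excluded by the splits once the pairs are kept. At an unadjusted p under 0.05 the counts were 5982 and at most 2194. The splits that part all 4 pairs number 8, too few for a share under 0.05; the highest other among them was 0, and 877 unadjusted.

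Astrocyte markers may be higher in tri-culture because RNA or cells of astrocytes were among the sorted cells, although sorting for GFP should remove unlabelled cells. In a second list of abundant astrocyte transcripts 82.35% (14 of 17) were higher, and 11 of 12 after CNN3 and genes of the first list were left out, as this explanation predicts. GFAP, among the most abundant, stood at 63.2, 151, 254 and 201 CPM in the 4 tri-culture libraries. Neurons as a source stay open, with 44.44% (4 of 9) of tested neuron markers higher. Only 9 of the 23 neuron markers in the list passed the filter on counts. The share therefore leaves out markers too low to test, which cannot count against neurons. Expression of these genes by the microglia themselves was not tested.

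For the MHC class II genes, shared reads between HLA genes as the whole cause are argued against, since 5 of the 5 pathway genes CIITA, CD74, HLA-DMA, HLA-DMB and HLA-DOA were higher, the smallest at a log2 fold change of 2.47. A common source with the astrocyte RNA is argued against over all 4 tri-culture libraries, since the log2 ratio of the indices varied with an SD of 0.6978, the astrocyte index by 1.55 and the class II index by 0.233. Much of this rests on library 1, with an astrocyte index of 3.90 against 4.81, 5.45 and 5.13 in libraries 2 to 4. The class II index was 8.56, 8.63, 8.43 and 8.67 in libraries 1 to 4. An interferon-gamma response stays open, with 18.75% (3 of 16) of its other targets higher and 5 lower. With the batch as a block 4 were higher (25%) and 6 lower. That share of higher targets no longer lies under the bound set for excluding it. Cells of dendritic type may contribute and stay open, with 53.85% (7 of 13) of dendritic genes higher without CD207, FCER1A and NDRG2. The missing cytokine supplement and the partner cells changed together, so their effects on these genes were not tested.

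For the cholesterol synthesis genes, dilution of microglial RNA by RNA of other cells is argued against, since the list's median lay at -1.444 relative to genes over 5 CPM in mono-culture. Sterol loading of the tri-culture microglia could lower them and stays open, with 30.77% (4 of 13) of LXR targets higher, between the bounds set in advance, and 5 of 13 lower (PLTP, FASN, SCD, NR1H3 and SREBF1). The cytokine supplement and the partner cells were not separated here either.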
